A study of Homo sapiens with 12 samples.

How the data were processed

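The series holds 12 spotted arrays with 2 channels each. Channel 1 holds RNA of time zero and channel 2 total RNA of fibroblasts at 0 minutes, 15 and 30 min, or 1, 2, 4, 6, 8, 12, 16, 20 or 24 h after serum, per the labels. Groups were taken from the channel 2 labels, with 1 array each. The labels give a lot number for every array, and the lots fall into 3 runs: 128 to 129, 318 to 324 and 407 to 416. That this is the lot in which the arrays were printed is a reading made here, on which every lot comparison rests.

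The deposited values are log2 ratios of the channels, read as such from the values themselves: they have both signs, centre near 0 and reach from -7.77 to 4.85, which excludes a linear ratio and would be extreme for log10. The base is assumed to be 2 by convention, and a natural log could not be told apart. The deposited tables state no background correction, normalization, dye or direction, and the scanning software is given as unknown per the labels. Array medians lay between -0.19 and 0.03 as deposited. Direction is called likely, as time point over time zero, from the order of the channels, the labelling of the study as published, and the positive early ratios of DUSP1 and JUNB, which were among the genes fixed beforehand. No arrays correlated below 0 over named genes.

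The arrays came in 2 tables of different array designs. The larger has 10 arrays and 9984 spots. The smaller has 15 min and 2 h and 10176 spots; it was normalized separately and entered no test. Neither held a missing value, so the planned filter (values on at least 8 arrays) removed nothing. The tables hold no spot brightness, so signal over background is unknown here, dim spots could not be set aside, and random gene lists were not matched on expression. The number of arrays limits the precision.

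Genes were named through the platform annotation. Of the larger design 4758 spots had 1 gene symbol, 189 several and 5037 none; in the smaller 5229 had none. Gene IDs of 4755 of the 4758 were found in the table of reference genes (assembly GRCh38.p14, used for names only), and 0 symbols changed. Spots with several symbols or none stayed as unnamed features. No coordinates are given, since the tables name no build.

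Each array was centred on its median, and spots of 1 gene were averaged, which gave 9410 features, 4184 of them genes and 499 of these with more than 1 spot. R 4.3.3 and limma 3.58.1 were used. With 1 array per time point, time points were pooled into windows: time zero (1 array), early (30 min and 1 h), middle (4, 6 and 8 h) and late (12, 16, 20 and 24 h). lmFit and eBayes fitted 1 coefficient per window to the 10 arrays, with 6 residual degrees of freedom. A p-value therefore measures whether a shift is shared by the times of a window, against a spread between times pooled over all windows, so that an array outside a comparison also moves its count. It does not measure biological replication. The 0 minute array is 1 array, subtracted in 3 of the comparisons and assumed to vary like the others. Adjusted p-values are Benjamini-Hochberg over all features, with a threshold of 0.05. Shifts carry the standard error of the fit.

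Lists of 708 genes in 25 groups were fixed before the data were examined, as were the comparisons, the naming rule and most alternatives. Of these 708 genes 166 were found among the named features, so each list stands for a part of its genes. The 14 lists with 5 or more measured members were tested with camera at a preset correlation of 0.01, adjusted within each comparison. Camera with an estimated correlation and fry, whose p tests whether a list moves on balance 1 way, were alternatives. The named genes are, per window against time zero, the 10 largest rises and 10 largest falls among genes past the threshold with every time of the window on 1 side. Where fewer than 3 passed, the 3 largest shifts are given as values. For late against middle the rule takes 6 each way, for the smaller table the 5 highest and 5 lowest per array, from each list up to 4 members, and in addition 24 genes fixed beforehand. Genes named because they passed within a list tell which members carried its count.

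The fit was tested on simulated data with 9410 features, 200 of them changed. A log2 shift of 2 was recovered in 91.5% of features in early against time zero, 94.5% in middle, 95.8% in late and 99.8% in late against middle. A shift of 1 was recovered in 13.4%, 21.6%, 23.2% and 78.5%. False calls were 4.9% to 5.38% of calls. Smaller changes against time zero would thus be missed. In late against middle, simulated lists of 15 genes were called in 4% of cases with no shift and 100% at a shift of 0.5. The simulated genes were drawn independently of each other, whereas the estimated correlation in the G2 and mitosis list was 0.64. The 4% therefore does not hold for lists of correlated genes.

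Alternatives were no centring, scaling to 1 median absolute deviation, quantile normalization, single spots, missing-value filters, robust eBayes, a 2-fold minimum, leaving out each array, ratios against 0, lot run terms and a spline in time. Chosen after seeing the data were named features alone, the first hour as baseline for the late window, 16 to 24 h against 4 and 8 h, and the lot run block outside late against middle. That block links the runs only through the late window, so it assumes that 12 h equals 16 to 24 h apart from the lot.  X-inactivation and Y-linked transcripts were kept in the fit and are not reported.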

Results

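Human fibroblasts were followed for 24 h after serum was added to them. Serum carries growth factors that bring resting fibroblasts back into the cell cycle, and the series asks which transcripts move as that happens. Total RNA of each of 12 time points was hybridised on 1 array against RNA of time zero: 0 minutes, 15 and 30 min, and 1, 2, 4, 6, 8, 12, 16, 20 and 24 h. The array of the 0 minute sample compares time zero with itself and gives the background. No time point has a second array, so no value has a replicate of its own. Each value is a log2 ratio, most likely of the time point over time zero, since the labels list time zero as channel 1, the study as published labelled its serum samples in red and time zero in green, and the early response genes fixed beforehand were positive early. Base 2 was assumed by convention, and the labels state neither base nor direction. If the base or direction is another, every fold and sign below changes with it.

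The number of features that stood 2-fold or more from time zero grew from the background to a peak at 8 h. Of 9410 features (a gene or an unnamed spot), 77 passed that size on the 0 minute array, 376 at 30 min, 485 at 1 h, 551 at 4 h, 562 at 6 h, 940 at 8 h, 764 at 12 h, 255 at 16 h, 305 at 20 h and 461 at 24 h. At 8 h 387 features were higher and 553 lower, and at 24 h 341 were higher and 120 lower. In the separately normalized table of 9602 features, 124 passed at 15 min and 205 at 2 h. The lot numbers in the labels, read here as array print lots although the labels do not say so, fall into 3 runs: 128 to 129 for 15 min and 2 h, 318 to 324 for 0 minutes and 16 to 24 h, and 407 to 416 for 30 min to 1 h and 4 to 12 h. The drop between 12 and 16 h falls on the step from lots 407 to 416 to lots 318 to 324. The rise from the 0 minute array to the 30 min array falls on the same step, taken the other way. The first hour and 4 to 8 h, set against time zero, thus lie wholly across these runs.

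**Figure D1:**
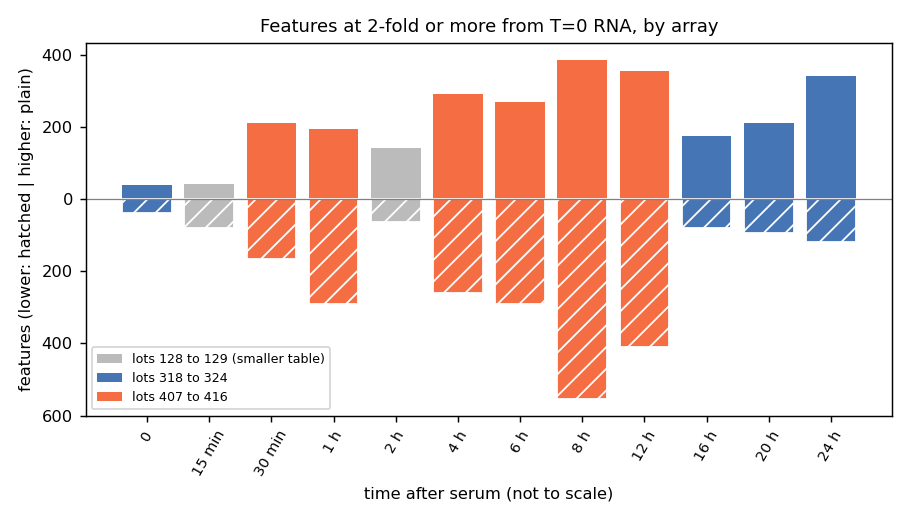
Number of features at 2-fold or more from time zero RNA on each of the 12 arrays (y axis; plain bars higher, hatched bars lower), against time after serum (x axis, not to scale), coloured by run of lots. The 8 h array has the most (387 higher, 553 lower) and the 0 minute array the fewest (40 higher, 37 lower); the 15 min and 2 h arrays belong to a separately normalized table.

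Within the first hour, genes of the immediate early response were higher than at time zero. The direction of the ratios was taken in part from the positive early ratios of DUSP1 and JUNB. The sign of this rise is therefore not an independent result. DUSP1, a phosphatase that switches off MAP kinases, was 6.24-fold higher in the 30 min and 1 h arrays than on the 0 minute array (log2 shift 2.64 ± 0.34 SE, adjusted p = 0.0104, n = 2 against 1). MCL1, an anti-apoptotic BCL2 relative, rose by a log2 shift of 1.76 ± 0.28 (adjusted p = 0.0337), and CCNL1, a cyclin of RNA splicing, by 1.69 ± 0.25 (adjusted p = 0.0185). Spots named DNPH1 and UNC79 rose by 2.77 and 2.49. The 13 measured immediate early factors rose as a list (median shift 0.73, 11 of 13 higher, camera adjusted p = 1.4e-05; adjusted p = 0.308 with an estimated correlation). Of them 1 passed over all features and 3 adjusted over the list alone: MCL1, NR4A2 and JUNB. JUNB, a partner in the AP-1 factor, shifted by 2.22 ± 0.47 and NR4A2, a nuclear receptor, was 7.98-fold higher (SE 0.66 on the log2 scale), with adjusted p of 0.146 and 0.194 over all features. No named gene passed as lower: the largest negative shifts were those of GLYATL1 at -1.88, SHISA7 at -1.80 and BACE1 at -1.60, with adjusted p of 0.0907, 0.155 and 0.0653. All 3 read 1.09 or more on the 0 minute array itself.

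In all, limma called 15 features in the early window, 15 higher and 0 lower, with 651 at an unadjusted p under 0.05 where chance gives 470. The split became 58 higher and 64 lower with arrays scaled to 1 spread and 59 and 70 after quantile normalization. With the lot run as a block 8 were called, none of the 5 named genes passed (DUSP1 at 2.39 ± 0.46, adjusted p = 0.161), and the immediate early list stood at adjusted p = 0.0552. That block assumes that 12 h equals 16 to 24 h apart from the lot, which does not hold for G2 and mitosis genes: they read -0.62 at 12 h and got an early median of 1.65 from the block. The count was 28 without the 30 min array, 24 without the 12 h array and 6 without the 20 h array. Without the 1 h array the immediate early list fell to a median shift of 0.32 (camera adjusted p = 0.0884). Of the 5 named rises DUSP1 alone passed whichever of the 9 later arrays was left out, and MCL1 passed in 3 of these 9 refits. Across 499 genes with more than 1 spot, the shifts of spots of the same gene correlated at r = 0.0582 across genes, which are not independent replicates, and at r = 0.369, 0.391, 0.324 and 0.32 in middle, late, late against middle and middle against early.

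At 4 to 8 h, 16 genes with a symbol were higher than on the 0 minute array, among them DUSP1, DNPH1, UNC79 and MCL1 of the first hour. PMEPA1, an inhibitor of TGF-beta signalling, was 5.98-fold higher than on the 0 minute array (log2 shift 2.58 ± 0.42 SE, adjusted p = 0.0227, n = 3 against 1). RGS4, which shortens G protein signals, rose by 2.54 ± 0.49 (adjusted p = 0.0437), and GPD1, a glycerol phosphate dehydrogenase, by 2.25 ± 0.37 (adjusted p = 0.0227). NET1, an exchange factor for RhoA, rose by 1.84, CLDN4, a tight junction claudin, by 1.75 and PHLDA1 by 1.82, while DUSP1 stayed 1.90 above the 0 minute array. Spots named DNPH1 and UNC79 were 2.07 and 1.85 above it, and CHTF8 was 1.95 above it because it read -1.47 there and 0.49 at 4 to 8 h.

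Among the genes that fell at 4 to 8 h were WEE1, the kinase that holds CDK1 inactive, by 1.95 (± 0.37, adjusted p = 0.0404), the nuclear receptor coactivator PNRC1 by 2.00 (± 0.36, adjusted p = 0.0349) and the formin DAAM1 by 2.02 (± 0.35, adjusted p = 0.0313). These 3 read between -0.34 and -0.06 on the 0 minute array. Another 7 named falls read high there: DAPK1 (shift -2.21), COL1A1 (-1.86), BACE1 (-1.67), PHF1 (-1.57), ZNF248 (-1.46), SDHAP3 (-1.45) and GSDME (-1.30) read between 0.87 and 1.23 on it. Against 0 in place of that array, COL1A1, the main chain of type I collagen, stood at -0.76 ± 0.14 (adjusted p = 0.00233), and CHTF8, ZNF248 and SDHAP3 no longer passed (adjusted p = 0.054, 0.233 and 0.0754).

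By list, the 5 measured growth factor and angiogenesis genes, of 34 listed, were all higher at 4 to 8 h. Their median shift was 0.69 (camera adjusted p = 0.00216, and adjusted p = 0.237 with an estimated correlation). None passed over all features and 2 adjusted over the list alone, NRG1 and VEGFA. VEGFA's 2 spots disagreed, at -0.06 and 1.91. The 8 MAP kinase phosphatases and feedback inhibitors rose (median 0.43, 7 of 8 higher, adjusted p = 0.00377; 0.164 as the adjusted p with an estimated correlation), with RGS4 and DUSP1 past the test over all features and DUSP6 in addition adjusted over the list alone, on 2 spots that disagreed (0.01 and 1.55). Cell cycle inhibitors and quiescence genes fell (median shift -0.39, 11 of 14 lower, adjusted p = 0.00445; adjusted p = 0.164 with an estimated correlation). Of these WEE1 passed over all features, and 4 passed adjusted over the list alone: WEE1, CDKN1B at -1.65 ± 0.47, CDKN1C at -0.95 and GAS1 at -0.84. CDKN1B encodes the CDK inhibitor p27, and GAS1 is known as a growth arrest gene, whereas WEE1 restrains entry to mitosis. Immediate early factors were still higher (median 0.65, adjusted p = 0.0358; adjusted p = 0.342 with an estimated correlation), with MCL1 past the test over all features and MCL1 and ID3 adjusted over the list alone. Cholesterol genes (median shift -0.39, 8 of 9 lower) and lipid and steroid genes (-0.24, 7 of 8 lower) fell, both with adjusted p = 0.0358 (adjusted p = 0.274 and 0.215 with an estimated correlation). Of their members 0 passed over all features, and ALDH3A2 of the lipid list adjusted over the list alone. Against 0 neither fall remained: the cholesterol median turned to 0.09 and the lipid median was -0.02 (adjusted p = 0.944 and 0.634).

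Against time zero 61 features were called at 4 to 8 h, 43 higher and 18 lower, and 95 and 99 with arrays scaled to 1 spread or 93 and 100 after quantile normalization. With the lot run as a block 7 were called and none of the 20 named shifts passed, though all 20 kept their sign with a median of 75.7% of their size. Of the lists that rose or fell, the cell cycle inhibitors alone passed with that block (adjusted p = 0.0447). The count was 9 without the 6 h array, 33 without 8 h, 31 without 16 h, 23 without 20 h and 148 without 12 h, and NET1 alone of the 20 named shifts passed whichever of the 9 later arrays was left out; the 0 minute array cannot be left out. Without the 4 h array the immediate early and lipid lists missed the threshold (adjusted p = 0.0794 and 0.071), without 6 h the lipid list (0.0678) and without 8 h the cholesterol list (0.128).

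The step from the first hour to 4 to 8 h can be read inside 1 run of lots and without the 0 minute array. RGS4 rose by 2.66 ± 0.39 (adjusted p = 0.00833) and GINS1, a subunit of the replicative helicase complex, by 1.29 ± 0.25 (adjusted p = 0.021). The nucleolar genes RRS1 and DKC1 rose by 1.39 ± 0.24 and 1.05 ± 0.19 (adjusted p = 0.015 and 0.0173), and ELN, which encodes elastin, by 1.11 ± 0.21 (adjusted p = 0.0184). NR4A2 fell by 2.11 ± 0.50 (adjusted p = 0.0384). Cell cycle inhibitors and quiescence genes fell (median shift -0.47, 11 of 14 lower, camera adjusted p = 0.00497; adjusted p = 0.181 with an estimated correlation). In that list WEE1 fell by 1.98 ± 0.29 (adjusted p = 0.00886), CITED2 by 1.00 ± 0.20 (adjusted p = 0.0245) and KLF9 by 0.92 ± 0.22 (adjusted p = 0.0427). Counted adjusted over the list alone, 5 fell, and GAS6, a ligand of receptor kinases known as a growth arrest gene, was higher (1.52 ± 0.40, adjusted p = 0.055 over all features). Lipid and steroid genes fell too (median -0.35, 7 of 8 lower, adjusted p = 0.0311; adjusted p = 0.181 with an estimated correlation), with 0 members past the test over all features and SCD, FADS2 and ALDH3A2 adjusted over the list alone.

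This step gave 391 called features, 174 higher and 217 lower. With the lot run as a block it gave 676, which is the same fit as leaving out the 12 h array. Both windows lie in 1 lot run, so the block corrects nothing in this step and only takes 12 h out of the spread. Without centring the arrays the split was 311 higher and 132 lower. The count was 34 without the 6 h array, 88 without 1 h, 178 without 30 min, 197 without 8 h, 201 without 16 h, 157 without 20 h and 676 without 12 h. The lipid list missed the threshold without the 30 min, 1 h or 6 h array (adjusted p = 0.0631, 0.0722 and 0.0632).

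From 12 to 24 h, 7 named genes were higher than on the 0 minute array and 4 lower. CXCL12, a chemokine, was 5.23-fold higher than on the 0 minute array (log2 shift 2.39 ± 0.28 SE, adjusted p = 0.00314, n = 4 against 1), with its 2 spots at 2.13 and 2.65. GPD1 was 6.74-fold higher (2.75 ± 0.36, adjusted p = 0.00809). ESPL1, the protease that parts sister chromatids, rose by 2.10 ± 0.33 (adjusted p = 0.029) and GINS1 by 1.81 ± 0.31 (adjusted p = 0.0328). TIMP3, an inhibitor of matrix proteases, rose by 1.78 ± 0.31, PLOD2, a collagen lysyl hydroxylase, by 1.64 ± 0.28 and ELN by 1.38 ± 0.25. Much of these rises was already present at 4 to 8 h. Window means at 4 to 8 h and at 12 to 24 h were 2.49 and 2.99 for GPD1, 1.53 and 2.08 for ESPL1, and 1.79 and 2.055 for GINS1. They were 1.77 and 1.94 for TIMP3, 1.21 and 1.89 for PLOD2, 1.17 and 1.51 for ELN, and 0.87 and 1.90 for CXCL12. PSAT1, an enzyme of serine synthesis, fell by 1.61 ± 0.26 (adjusted p = 0.0299), GASK1B by 1.48 ± 0.25, the claudin CLDN11 by 1.39 ± 0.23 and DHCR7, which makes cholesterol from its last precursor, by 1.31 ± 0.23 (adjusted p = 0.0362). The extracellular matrix list did not move as a whole (median -0.02, 8 of 16 higher, adjusted p = 0.958): PLOD2 and ELN passed over all features, and COL1A1 at -0.86 and LUM at -0.94 were lower adjusted over the list alone. COL1A1 read 1.10 on the 0 minute array and 0.24 in the late window, so its late fall rests on that 1 array. DHCR7 read 0.76 on the 0 minute array and -0.55 in the late window.

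The 9 measured cholesterol genes were lower late (median shift -0.68, 8 of 9 lower, camera adjusted p = 1.19e-05; adjusted p = 0.104 with an estimated correlation). DHCR7 passed over all features and 4 passed adjusted over the list alone: DHCR7, IDI1 at -1.86 ± 0.44, CYP51A1 at -1.17 ± 0.26 and SC5D at -1.11 ± 0.41. Genes of replication and S phase rose (median 0.84, 10 of 13 higher, adjusted p = 4.2e-05, and adjusted p = 0.177 with an estimated correlation). Against 0 that list passed with a smaller median (0.43, adjusted p = 0.0204). GINS1, which already read 1.79 at 4 to 8 h, passed over all features and 6 genes adjusted over the list alone. Among these were the flap nuclease FEN1 at 2.01 ± 0.54 and the ribonucleotide reductase subunit RRM2 at 1.78 ± 0.61. Genes of G2 and mitosis rose as a list (median 1.23, 13 of 15 higher, adjusted p = 1.98e-05; adjusted p = 0.327 with an estimated correlation), with 0 members past the test singly, over all features or over the list alone. TOP2A, the DNA topoisomerase of dividing cells, shifted by 1.70 ± 0.86, CDK1 by 1.62 ± 0.76 and CCNB1, its cyclin partner, by 1.23 ± 0.58. The list's own median was -0.66 on the 0 minute array, and against 0 it did not pass (median 0.46, adjusted p = 0.0962). It read -0.62 at 12 h, 0.25 at 16 h, 0.63 at 20 h and 1.29 at 24 h. Chaperones and endoplasmic reticulum stress genes rose (median 0.54, 7 of 9 higher, adjusted p = 0.00408, and adjusted p = 0.177 with an estimated correlation). Over all features 0 members passed. HSP90B1, a chaperone of the endoplasmic reticulum, passed adjusted over the list alone (1.18 ± 0.30). It read -0.97 on the 0 minute array, with means of -0.40 in the first hour and -0.70 at 4 to 8 h. Its low start thus does not rest on the 0 minute array alone.

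The late window gave 38 called features against time zero, 29 higher and 9 lower, and 116 and 122 with arrays scaled to 1 spread or 104 and 144 after quantile normalization. With the lot run as a block, here 16, 20 and 24 h against 0 minutes inside lots 318 to 324, it gave 53, and all 11 named genes and 4 lists passed there. With the first hour as the baseline, an alternative chosen after seeing the data, 664 were called, 308 higher and 356 lower. Of these 24 were among the 38. The count was 10 without the 20 h array, 13 without 16 h, 17 without 6 h, 19 without 24 h and 23 without either 30 min or 1 h. GPD1 and CXCL12 passed whichever of the 9 later arrays was left out.

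**Figure D2:**
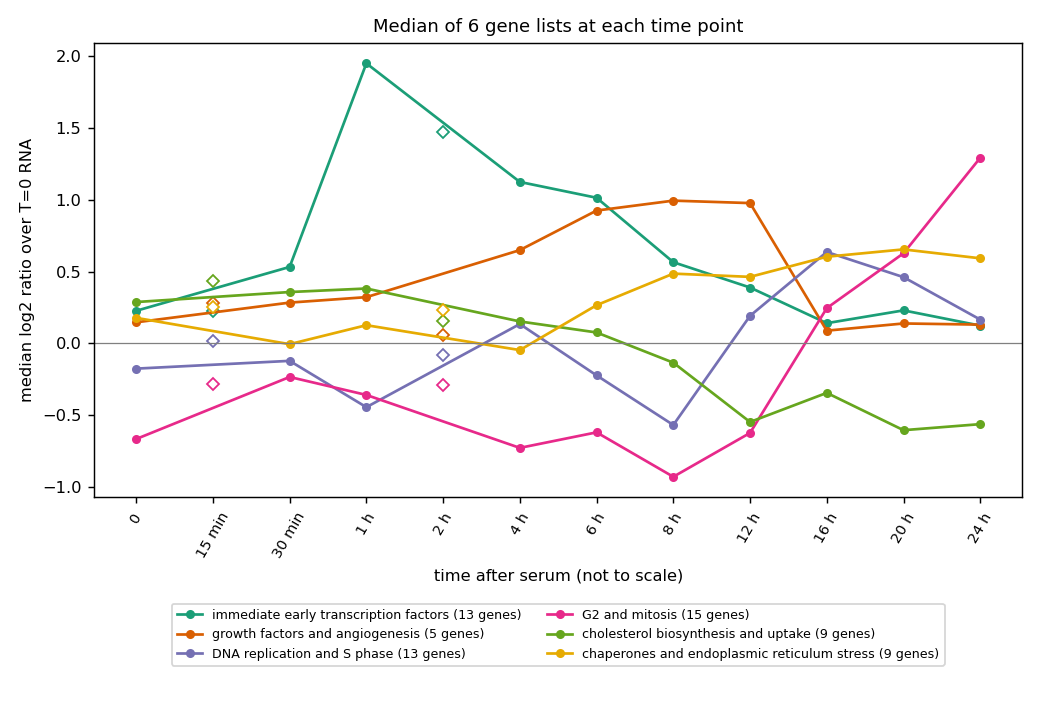
Median log2 ratio over time zero RNA (y axis) of 6 of the gene lists at each time after serum (x axis, not to scale); filled points and lines are the 10 arrays of the larger table, open diamonds the 15 min and 2 h arrays of the separately normalized one. The immediate early list peaks at 1.95 at 1 h, the growth factor list at 0.99 at 8 h, and the G2 and mitosis list reaches 1.29 at 24 h from -0.66 on the 0 minute array.

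Set directly against 4 to 8 h, 60 genes with a symbol were higher at 12 to 24 h and 90 lower. ARRDC4, an arrestin-domain gene induced by the same glucose sensor as TXNIP, was 5.31-fold higher (log2 shift 2.41 ± 0.30 SE, adjusted p = 0.00474, n = 4 against 3), and TXNIP, a thioredoxin inhibitor, rose by 1.72 ± 0.22 (adjusted p = 0.00474). FEN1 rose by 2.02 ± 0.37, the ubiquitin-conjugating enzyme UBE2T by 1.86 ± 0.34, WEE1 by 1.74 ± 0.25 and GMNN, the geminin that limits replication origins, by 1.69 ± 0.22. TXNIP went from a mean of -2.15 to -0.44 and WEE1 from -2.29 to -0.54, so both stayed below 0, whereas ARRDC4, FEN1, UBE2T and GMNN ended above it. TXNIP read -1.345 on the 0 minute array itself. STC1, a secreted glycoprotein hormone, fell by 2.16 ± 0.39 (adjusted p = 0.0199) and PMEPA1 by 2.04 ± 0.28 (adjusted p = 0.00681). SCD, the stearoyl-CoA desaturase, fell by 1.78 ± 0.28, ABRAXAS2 by 1.76 ± 0.33, CLDN4 by 1.48 ± 0.17 and IDI1, an isomerase of cholesterol synthesis, by 1.46 ± 0.30. MCL1 fell by 1.24 ± 0.17 (adjusted p = 0.00681). VEGFA was called lower at -1.15 ± 0.21 (adjusted p = 0.0198) on 2 spots that stood at -2.03 and -0.28.

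Genes of G2 and mitosis rose between these windows (median shift 0.93, 14 of 15 higher, camera adjusted p = 0.000233; adjusted p = 0.272 with an estimated correlation). None of them passed over all features; 9 were higher and 1 lower adjusted over the list alone, among them MAD2L1 of the spindle checkpoint at 2.29 ± 0.57 and TOP2A at 2.08 ± 0.58. Replication and S phase genes rose (median 0.37, 12 of 13 higher, adjusted p = 0.0166), as did chaperones (0.33, 8 of 9 higher, adjusted p = 0.0192). Growth factor genes (median -0.65, 4 of 5 lower), immediate early factors (-0.24, 9 of 13 lower) and cholesterol genes (-0.47, 6 of 9 lower) fell, each with adjusted p = 0.0192. With an estimated correlation these other 5 lists all had adjusted p = 0.271. Over all features FEN1 and GMNN passed in the S phase list, HSP90B1 among the chaperones, VEGFA among the growth factors, MCL1 and ID1 among the immediate early factors, and IDI1 and CYP51A1 among the cholesterol genes. Adjusted over the list alone, 5 S phase genes were higher and 1 lower, 1 chaperone was higher, and 3 growth factors, 3 immediate early factors and 4 cholesterol genes were lower.

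This comparison called 312 features, 141 higher and 171 lower (98 and 216 without centring), but it lies largely across the lot runs. With the lot run as a block, the same estimate as 12 h alone against 4 to 8 h, 16 were called, 1 higher and 15 lower, of which 2 were among the 312. None of the 12 named shifts passed there: they kept a median of 70.1% of their size and their sign, with SEs at a median of 1.25 times the unblocked ones and adjusted p from 0.0836 (CLDN4) to 0.365 (STC1). FEN1 went from 2.02 to 0.84, UBE2T from 1.86 to 0.78, STC1 from -2.16 to -1.07 and SCD from -1.78 to -0.98. Cholesterol genes passed with the block (median -0.35, adjusted p = 0.0442) and G2 and mitosis did not (median 0.11, adjusted p = 0.858). Nor did growth factors (median 0.01, adjusted p = 0.858) and S phase genes (0.18, adjusted p = 0.393). Chaperones (0.16, adjusted p = 0.27) and immediate early factors (-0.14, adjusted p = 0.324) were lost as well. The count was 23 without the 6 h array, 24 without 20 h, 43 without 24 h, 55 without 16 h, 88 without 4 h and 1341 without 12 h. The balance turned to more rises without 12 h (827 higher, 514 lower) and for 16 to 24 h against 4 and 8 h, chosen after seeing the data (302 higher, 215 lower). ARRDC4, WEE1, TXNIP, GMNN, PMEPA1 and CLDN4 passed whichever of the 9 later arrays was left out. Without the 4 h array the cholesterol and chaperone lists missed the threshold (adjusted p = 0.0593 and 0.104), without 8 h the S phase and growth factor lists (0.0589 and 0.071), and without 12 h the cholesterol list (0.0731).

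**Figure D3:**
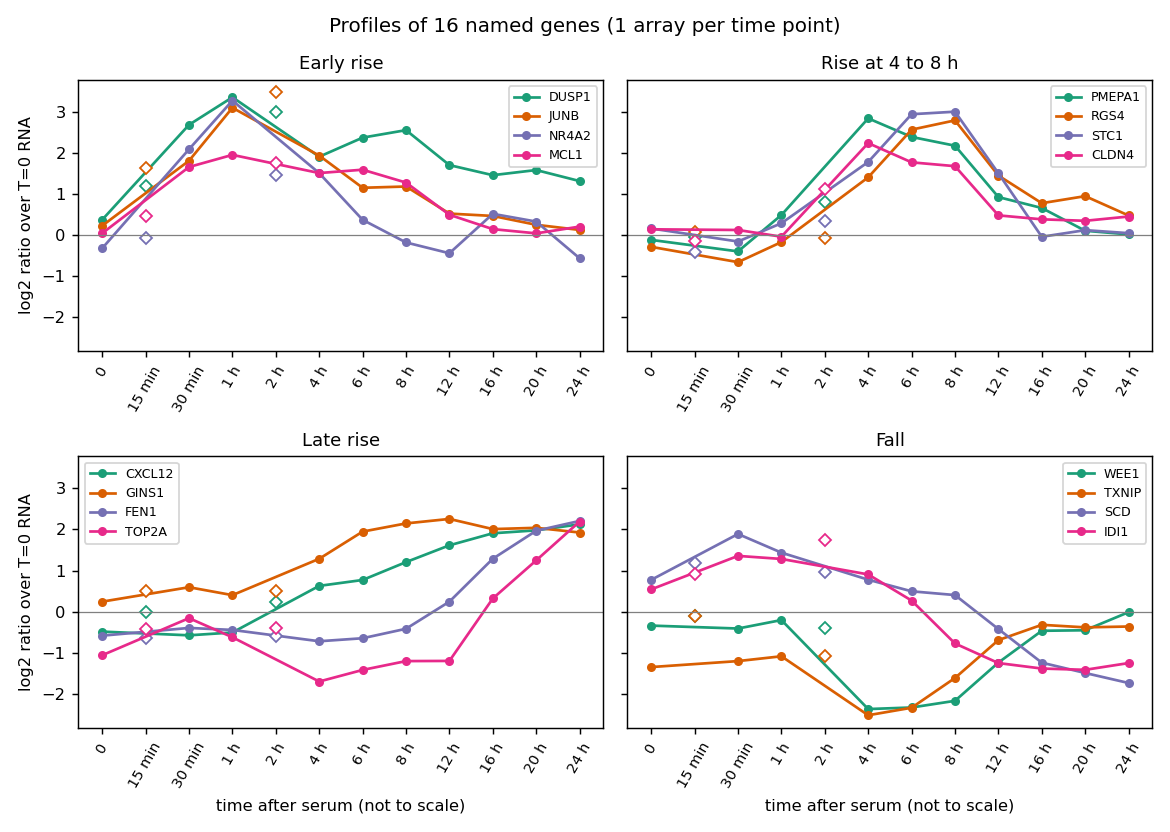
Log2 ratio over time zero RNA (y axis) of 16 named genes on 12 arrays, 1 per time after serum (x axis, not to scale), in 4 panels; filled points and lines are the 10 arrays of the larger table and open diamonds the 15 min and 2 h arrays of the other. DUSP1 reaches 3.35 at 1 h, STC1 2.93 at 6 h and FEN1 2.20 at 24 h, and WEE1 falls to -2.36 at 4 h and returns to -0.01 at 24 h. GINS1, drawn with the late rises, already has a mean of 1.79 at 4 to 8 h.

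In the separately normalized pair of arrays, read as values with no test, JUNB was already at 1.64 at 15 min and at 3.47 at 2 h. DUSP1 read 1.18 at 15 min and was among the 5 highest at 2 h. DNPH1 read 1.93 and 3.36, and UNC79 1.96 and 2.91. ID3, an inhibitor of basic helix-loop-helix factors, read 0.21 at 15 min and 3.07 at 2 h. NIT1, and GPNMB at 1.43, completed the 5 highest named genes at 15 min. The lowest at 15 min were BAK1 at -2.13, APLNR at -2.08, OGN at -1.32, CENPN at -1.28 and AKAP9 at -1.22, and at 2 h LILRB2 at -2.16, WDR20 at -1.83, FAM53B at -1.83, ARMH4 at -1.47 and LINC02893 between these. BAK1 and APLNR read 0.01 and -0.27 at 2 h in the same table, and 0.52 and 0.17 at 30 min in the larger one.

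Of 24 genes fixed beforehand for naming, 9 were measured, and the others, FOS, MYC and PCNA among them, were not analysed here. CDKN1A, which encodes the CDK inhibitor p21, read 1.08 on the 0 minute array, 0.96 at 4 to 8 h and 0.57 at 12 to 24 h, with no shift past the test (late adjusted p = 0.689). PLAUR, the urokinase receptor, shifted by 0.53 early, 0.56 at 4 to 8 h and 0.96 ± 0.25 late (adjusted p = 0.785, 0.498 and 0.186). Of the other lists at 4 to 8 h, actin cytoskeleton genes had a median shift of 0.25 (adjusted p = 0.196), extracellular matrix genes -0.17 (adjusted p = 0.412), translation factors 0.08 (adjusted p = 0.632) and the proteasome 0.24 (adjusted p = 0.286). Against 0 the actin list passed there (median 0.37, adjusted p = 0.00566) and in the first hour (0.18, adjusted p = 0.0138). Its median was 0.20 on the 0 minute array itself. The 5 nucleolar genes had a median of -0.26 and a mean of 0.15 at 4 to 8 h, so that their sign is not settled (adjusted p = 0.618). An F test over the 3 windows against time zero called 637 features.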

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

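The tests of the G2 and mitosis rise inside 1 lot run and of the 0 minute array's share were chosen after their results were partly seen; the splits of the arrays and the check on 12 h against 6 h were set before their values were seen, though after the blocked count was known. The results here drew attention because a test of the difference between windows was passed. Between late and middle these were the shifts of ARRDC4 (2.41), FEN1 (2.02), UBE2T (1.86), WEE1 (1.74), TXNIP (1.72), GMNN (1.69), STC1 (-2.16), PMEPA1 (-2.04), SCD (-1.78), ABRAXAS2 (-1.76), CLDN4 (-1.48) and IDI1 (-1.46). The lists were G2 and mitosis (median 0.93), replication and S phase (0.37), chaperones (0.33), growth factors (-0.65), cholesterol (-0.47) and immediate early factors (-0.24), and all 6 were lost with an estimated correlation (adjusted p = 0.272 for G2 and mitosis and 0.271 for the others). Between middle and early they were cell cycle inhibitors and quiescence (-0.47) and lipid and steroid metabolism (-0.35), read inside 1 lot run and both lost with an estimated correlation (adjusted p = 0.181).

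The late against middle difference may be the serum response going on or may come from the lots, since 16, 20 and 24 h are from other lots than 4 to 8 h. Of the 35 splits of these 7 arrays 2 called as many features. They are the real one with 312, and the split of 4 to 12 h from 16 to 24 h with 1113. The second is the lot runs themselves, and both part the arrays in order of time. Every other split called 0. By the bound set beforehand, 2 of 35 is too many to exclude a chance split of the arrays. Calls confined to these 2 splits point to a structure of the samples, which may be time or lot. Among 517 features called between 16 to 24 h and 4 and 8 h, 75% had the same sign in 12 h against 6 h, 2 arrays of 1 run left out of that call (95% exact binomial interval 71.1 to 78.7, against 60.6% of all features), so the bound set beforehand, at least 75%, was just met. The interval counts co-regulated features on the same 2 arrays as independent, so it is too narrow; it still reaches below the bound, and that the interval must clear it was asked only after the value was seen, so the lot is left open. Features selected as 2-fold or more at 4 and 6 h kept 74.8% (higher) and 81.8% (lower) of their median ratio at 12 h and 41% and 27.6% at 16 h, so time and lot cannot be told apart for the count as a whole. For G2 and mitosis the lot step as the whole cause is argued against: inside lots 318 to 324 its 15 members were all higher at 24 h than at 16 h, by a median of 1.18 (SD over members 0.417).

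Falls against time zero may in part be high readings of the single 0 minute array. Over the 18 features called lower at 4 to 8 h, that array's own ratio made up a median of 62.4% of the shift, and 12 of them read 0.8 or more on it, whereas it made up 4.57% in the 43 called higher. Over the 9 called lower late the share was 25.7%, which leaves that window open. These readings are not shown to be error. Over named genes the 0 minute array correlated with every other array (r = 0.193 to 0.419 across genes). All arrays share time zero RNA in channel 1, and no value of r without a true signal is known, so r cannot decide this. A spot or dye effect shared by all arrays would make subtracting the 0 minute array right. The cause therefore stays open. WEE1, PNRC1 and DAAM1 read below 0 on that array.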

How the results depend on the processing

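No paired analysis was possible because each time point has 1 array and the labels carry no replicate numbers. No named shift and none of the 19 called lists passed in the other direction under an alternative. For the other called features the signs were not compared. The medians of 2 called lists changed sign: cholesterol in the middle window against 0 (0.09 from -0.39) and growth factors in late against middle with the lot block (0.01 from -0.65). The missing-value filters removed nothing, so they test nothing. Alternatives chosen after seeing the data are named features alone, the early baseline, 16 to 24 h against 4 and 8 h, and the lot block outside late against middle. Counts against time zero (main values 15 early, 61 middle and 38 late) became 122, 194 and 238 with arrays scaled to 1 spread. They became 129, 193 and 248 after quantile normalization, and 951, 2632 and 2489 against 0. Named features alone gave 6, 36 and 11, where the main fit called 5, 27 and 11 genes with a symbol. Against 0 no single array is subtracted, which lowers the standard error (DUSP1 early from 0.344 to 0.199, GPD1 late from 0.360 to 0.161). Whether that accounts for the whole gain against 0 was not tested, nor was the cause for the rescaled arrays. With the lot block early gave 8 and middle 7. The early baseline gave 664 in the late window, 24 of them shared. Late against middle (312) gave 138 at 2-fold or more, 16 with the lot block or with 12 h alone, which are the same estimate, and 517 (302 higher, 215 lower) for 16 to 24 h against 4 and 8 h. Middle against early (391, of them 172 genes with a symbol) gave 198 among named features alone. It gave 676 with the block, which is the same fit there as leaving out 12 h. The spline called 1242 features against 637. Leaving out each of the 9 arrays after 0 minutes gave 6 to 28 early, 9 to 148 middle, 10 to 53 late, 23 to 1341 late against middle and 34 to 676 middle against early, and lists past the test numbered 0 to 1, 4 to 6, 4 to 7, 4 to 7 and 1 to 5. With an estimated correlation 0 lists passed in each of the 5 comparisons, so all 19 list calls were lost. With fry 0 passed early, 3 in the middle and 2 late, and 8 calls were lost. The 2 late lists were cholesterol and lipid and steroid metabolism, of which the latter was not called in the main fit. Late G2 and mitosis (fry adjusted p = 0.315), S phase (0.0733) and chaperones (0.083) were lost. G2 and mitosis in late against middle was lost too (fry adjusted p = 0.0907). With the lot block 3 passed in the middle and 1 in late against middle, and 11 calls were lost. Of those 3 middle lists the cell cycle inhibitors alone were called in the main fit. S phase (median 0.49, camera adjusted p = 0.00089) and G2 and mitosis (1.20, camera adjusted p = 7.8e-07) were called higher only with the block. For G2 and mitosis the block's assumption does not hold: the list read -0.62 at 12 h and 0.25, 0.63 and 1.29 at 16, 20 and 24 h. Its median shift without the block was 0.03, so that call comes from the block. S phase read 0.19 at 12 h and 0.64, 0.46 and 0.17 at 16, 20 and 24 h, which leaves the assumption in doubt. Of the refits of named shifts without 1 array, 272 stayed past the threshold and 160 did not. At 3-fold in place of 2-fold the arrays had 30 (0 minutes), 29 (15 min), 82 (30 min), 94 (1 h), 68 (2 h), 97 (4 h), 128 (6 h), 185 (8 h), 159 (12 h), 71 (16 h), 71 (20 h) and 114 (24 h) features. Without centring the counts were 263 at 15 min, 427 at 30 min and 613 at 1 h, and with the 0 minute array subtracted 503 at 4 h, 502 at 6 h, 787 at 8 h and 672 at 12 h. Signal over background is unknown here, so no limit can be set from it.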

Other observations

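The test on DUSP1 was chosen after its result was partly seen. Several lists had too few measured genes for a test, and their members are given as values. Of the cytokines and inflammation list, CXCL12 rose late, while NAMPT, an enzyme of NAD synthesis, read 0.95 at 1 h, 1.61 at 4 h and -0.08 at 12 h and was lower late than at 4 to 8 h (shift -1.37 ± 0.31, adjusted p = 0.038). SOD2, the mitochondrial superoxide dismutase, was lower in that comparison too (-0.76 ± 0.18, adjusted p = 0.0466), and IL15 was not called (0.30, adjusted p = 0.437). Of the proteolysis list, TIMP3 and PLAUR are described with the main comparisons, THBS1 stood at -0.53 (adjusted p = 0.271) and MMP14 at 0.18 (adjusted p = 0.557) in late against middle. PFKFB3, a switch enzyme of glycolysis and the glycolysis gene measured, read 1.54 at 2 h, 1.52 at 4 h and -0.10 at 12 h and was lower late than at 4 to 8 h (-1.11 ± 0.20, adjusted p = 0.0199). CDK6 of the G1 kinases (-0.45, adjusted p = 0.248), the ribosomal protein gene RPL37A (0.29, adjusted p = 0.392), and BST2 and IFI44 of the interferon list (-0.52 and 0.23, adjusted p = 0.173 and 0.566) were not called there. These late against middle values lie largely across the lot runs.

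Markers of other cell types were few, and no such list could be tested. KIT, fixed as a melanocyte marker and a receptor tyrosine kinase, fell from the first hour to 4 to 8 h (-2.52 ± 0.48, adjusted p = 0.0189), inside 1 lot run, and read -3.33 at 6 h and -1.23 at 24 h. MLANA, the other melanocyte marker measured, stood at -0.20 (adjusted p = 0.817) in that comparison. The keratinocyte marker PKP1 (0.45, adjusted p = 0.439), the endothelial markers CDH5 and CLDN5 (0.17 each, adjusted p = 0.691 and 0.692), the leukocyte markers PTPRC and LAPTM5 (0.16 and 0.08, adjusted p = 0.803 and 0.858) and the red cell marker ALAS2 (0.40, adjusted p = 0.587) were not called.

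Spots named DNPH1 and UNC79 followed DUSP1 over the 10 arrays of the larger table, at ranks 3 and 1 of 9409 features by correlation (r = 0.969 and 0.982 across arrays that were also used to rank them). A candidate explanation is that these spots hold DUSP1 sequence. In the smaller table, which took no part in the ranking, both lay within 0.771 of DUSP1 on the log2 scale at 15 min and 2 h. That meets what the explanation needs, but genes under common control would meet it too, and no spot sequence was used here.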
